A study of Homo sapiens with 8 samples.

How the data were processed

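Polyadenylated RNA was sequenced from LoVo and HCT116, human colorectal cancer cell lines, in 4 groups of 2 libraries each. The LoVo groups received a control antisense oligonucleotide or one against circ86591 at 30 nM (the dose of the control is not stated), and the HCT116 groups were infected with a control vector or with one carrying circ86591. Nothing in the labels says that replicates were separate cultures. The p values of single genes therefore measure only the spread between these samples, which may be technical. The library protocols of the knockdown and overexpression libraries differed per the labels.

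The LoVo table holds TPM as deposited by the authors, for 20263 genes, nearly all protein-coding, of which 20224 had an entry in GENCODE 29. Each LoVo library sums to the same fixed total, mitochondrially encoded genes included, so its depth is unknown. The HCT116 table holds FPKM (fragments scaled by gene length and library size) as deposited by the authors, for 58735 genes with coordinates, gene length and gene type. FPKM multiplied by gene length gave whole reads within 0.01 for 100% of values, at 13901034, 12233446, 12583386 and 12553097 reads in the 4 libraries. The build, GRCh38 (hg38), and the read tools FastQC 0.11.2, Trimmomatic 0.36 and fastp (no version) are named in the submitters' processing notes. The aligner and the quantifier are not given in the sources used here.

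Each cell line was fitted alone, since each table holds 1 line and the tables were normalized separately. Values were taken as log2(value + 1), which understates the change of genes with low values. Genes at 1 or more in at least 2 of the 4 libraries were tested with limma 3.58.1 (linear model, empirical Bayes with a mean-variance trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. With 2 libraries against 2, an exact permutation test of a single gene cannot go below 0.333. Gene lists with at least 4 tested members were tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated from the data. At the preset correlation genes are the units, so its p values mostly measure spread across genes and not between libraries. With 2 libraries in each group the estimated correlation leaves so few degrees of freedom that almost no list could pass. The HCT116 mitosis list, with an estimated correlation of 0.0612, had an unadjusted camera p of 0.0318 there. In LoVo as deposited the estimates were far above the preset, from 0.584 (histones) to 0.980 (G1/S) among the 12 lists that passed at the preset. The LoVo p values at the preset correlation therefore rest on a value far below these estimates. Failing the test with the estimated correlation does not decide whether a list changed. The groups of a gene were counted as not overlapping when both treated libraries lay on 1 side of both controls, and chance gives 33.3%.

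The 36 gene lists, the tests, the rule for named genes and the first set of alternatives were fixed before the data were examined. Named genes were those of the CDKN2B-AS1 locus, and the 8 protein-coding genes per direction with the largest change among those past the threshold, with a mean of 5 or more in the higher group and groups that do not overlap. Where fewer than 8 passed, the places went to the smallest unadjusted p, and for each list described up to 4 members with the smallest unadjusted p were named. Some genes that this rule takes are not reported here. That set held a pseudocount of 0.1, no filter, a filter at a mean of 5, median-of-ratios scaling, quantile normalization, no trend, protein-coding genes alone, a replicate block, each library left out in turn, a fold of at least 2 and the estimated correlation. After the data were seen, further alternatives were added. For LoVo these were removal of the mitochondrially encoded genes, and median-of-ratios scaling together with a replicate block, with each library left out, with a correction for gene length, or with a correction for gene length and GC content (loess, span 0.3). For HCT116 they were limma voom on the recovered reads (genes with 10 or more reads in at least 2 libraries), the same with a replicate block or with each library left out, and the correction for gene length and GC content. Where 1 library was left in a group, it was assumed to vary like the other group.

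The pipeline was tested on simulated data with 200 changed genes built from the means, fitted spreads and library factors of these tables. On TPM as deposited it called 0% of the genes changed 4-fold in LoVo, and with median-of-ratios scaling 84.8% of those changed 4-fold and 4.48% of those changed 2-fold, with 4 false calls. In HCT116 it called 95.5% of the genes changed 1.5-fold on log2 FPKM, with 22 false calls, and 97.0% with voom, with 12 false calls. The reads simulated for voom had an assumed coefficient of variation of 5% beyond counting error. Changed genes were drawn only from those with higher values, so recovery at low values was not tested. Noise was independent between genes, and gene length and GC trends were left out, so false calls in the real libraries may be more frequent. Except for the voom reads, the spreads drawn were those already shrunken by empirical Bayes, so the recovery rates may be too high. In the real HCT116 libraries 0 of 14338 genes passed on log2 FPKM. That count does not show that no gene changed 1.5-fold.

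Of the 36 lists, 31 had enough tested members in each line and 12 passed camera in each, as described with the results. In LoVo the other tested lists did not pass: cyclin D and CDK inhibitors (adjusted p 0.612, median below and test above other genes), p53 targets (0.511, median below and test above), MYC targets (0.655), endoplasmic reticulum chaperones (0.933), heat shock proteins (0.103), immediate early and ERK output (0.689), FOXO targets (0.612), TGF-beta and BMP targets (0.303), YAP targets (0.673, median above and test below), epithelial markers (0.655), mesenchymal markers (0.0593), intestinal differentiation (0.612), hypoxia (0.126), glycolysis (0.933), cholesterol synthesis (0.673), fatty acid synthesis (0.689), nuclear oxidative phosphorylation (0.944), apoptosis (0.673) and lysosome and autophagy (0.511). In HCT116 the lists that did not pass were cyclin D and CDK inhibitors (0.765), G1/S and DNA replication (0.765), homologous recombination (0.534), heat shock proteins (0.991), NF-kB (0.369), immediate early and ERK output (0.668), FOXO targets (0.765), TGF-beta and BMP targets (0.533), YAP targets (0.354), mesenchymal markers (0.765), hypoxia (0.534), glycolysis (0.765), fatty acid synthesis (0.0555), NRF2 targets (0.765), nuclear oxidative phosphorylation (0.310), mitochondrially encoded genes (0.768), apoptosis (0.355), splicing factors (0.0554) and lysosome and autophagy (0.355). With voom, 3 further lists passed in HCT116: fatty acid synthesis (below other genes, adjusted p 0.00310, and adjusted p = 0.379 with an estimated correlation), splicing factors (below, 0.0109 and 0.323) and the CDKN2 locus, which includes CDKN2B-AS1 (above, 0.000837 and 0.299), which had too few members on log2 FPKM. Reads of the vector could count toward CDKN2B-AS1. Fatty acid synthesis also passed below with protein-coding genes alone (0.0251 and 0.424) and the length and GC correction (0.0182 and 0.503). Splicing factors did so with those (0.0253 and 0.398, 0.0319 and 0.409) and with no filter (0.0183 and 0.414). Above, glycolysis passed with quantile normalization (0.00292 and 0.306) and the CDKN2 locus with no filter (0.00738 and 0.414). In LoVo, heat shock proteins passed below other genes with quantile normalization (0.00354, and adjusted p = 0.635 with an estimated correlation) and with the length and GC correction (0.0170 and 0.648). They also passed below with no trend (0.0237 and 0.969), with mitochondrially encoded genes removed (0.0490 and 0.958) and with the length correction (0.0365 and 0.682). Without knockdown replicate 2 the heat shock list lay below other genes too. The endoplasmic reticulum chaperones passed above other genes without knockdown replicate 1 (0.00497, and adjusted p = 0.980 with an estimated correlation) and below without knockdown replicate 2 (0.0116 and 0.982). Without knockdown replicate 1, hypoxia (0.00497), cholesterol synthesis (0.0204) and lysosome and autophagy (0.0239) also passed above other genes as deposited, each with adjusted p = 0.980 with an estimated correlation. Hypoxia passed above with quantile normalization (0.0475, and adjusted p = 0.635 with an estimated correlation) and the length correction (0.0450 and 0.682) too. Mesenchymal markers passed above without control replicate 2 (0.0185, and adjusted p = 0.992 with an estimated correlation) and without knockdown replicate 2 (0.000198 and 0.982).

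The lists with fewer than 4 tested members were not tested. In LoVo these were the CDKN2 locus, leukocyte markers (3 members past the filter, the highest CD74 at 723 TPM), endothelial markers (ESAM at 12.2 TPM), neuroendocrine markers (SCG2 at 10.4 TPM) and nuclear long noncoding RNAs. In HCT116 these were the CDKN2 locus, leukocyte markers (HLA-DRA at 5.78 FPKM), endothelial markers (ESAM at 2.18 FPKM), neuroendocrine markers (SCG2 at 13.2 FPKM) and intestinal differentiation (CA2 at 14.1 FPKM). With no filter the LoVo leukocyte list was tested and passed above other genes (adjusted p 1.49e-08, and adjusted p = 0.802 with an estimated correlation). KEGG pathways with at least 10 tested genes were tested with camera after the results were seen.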

Results

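RNA was sequenced from 2 human colorectal cancer cell lines treated to lower or to raise a circular RNA, whose own level was not measured here. The circular RNA, circ86591, is named after the antisense transcript of the CDKN2B locus (hsa_circCDKN2B-AS_012), and the design asked which signaling pathways it uses to regulate proliferation. LoVo cells received an antisense oligonucleotide (ASO) against circ86591 at 30 nM (n = 2) or a control oligonucleotide (n = 2). HCT116 cells were infected with a vector, abbreviated ADV in the labels, carrying circ86591 (n = 2) or with its control (n = 2). The LoVo values were TPM for 20263 genes, which keep no record of depth. In HCT116 the FPKM of 58735 genes gave back whole reads, 13901034 and 12233446 in control replicates 1 and 2 and 12583386 and 12553097 in overexpression replicates 1 and 2.

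The mitochondrially encoded genes, which make subunits of the respiratory chain, took very different shares of the LoVo libraries. They held 18.2% and 48.3% of all TPM in control replicates 1 and 2, and 73.6% and 20.8% in knockdown replicates 1 and 2. In HCT116 they held 35.0%, 34.5%, 35.1% and 34.9% of FPKM. Knockdown replicate 1 therefore had little TPM left for every other gene. The median log2 change over all tested LoVo genes was −0.70 as deposited and −0.03 once each library was rescaled to a common median gene (median-of-ratios). LoVo changes below are given on the rescaled values unless stated.

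**Figure D1:**
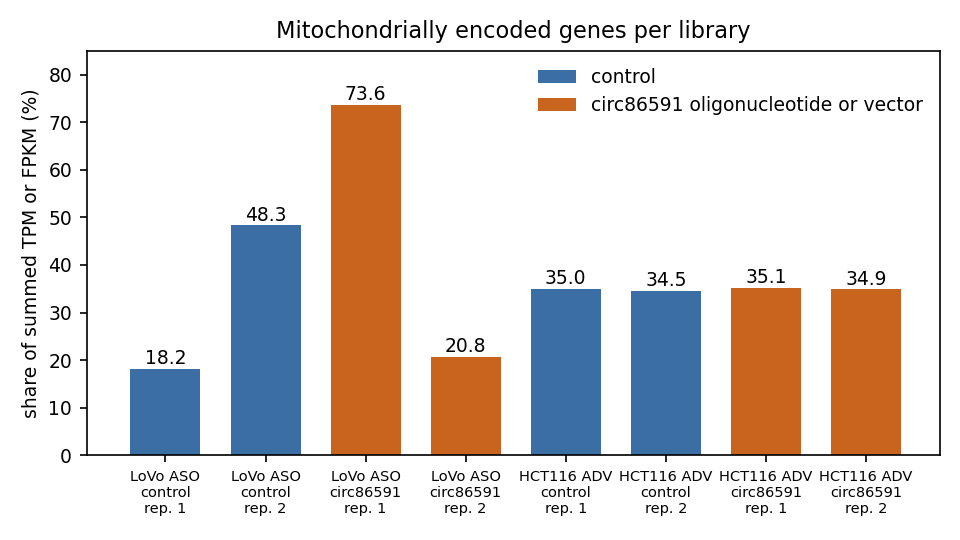
Share of the deposited total (percent, bars) held by the 13 mitochondrially encoded genes in each of the 8 libraries. LoVo libraries ran from 18.2% to 73.6%, with the highest value in knockdown replicate 1, and HCT116 libraries from 34.5% to 35.1%.

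The host gene of the circle was examined first. CDKN2B-AS1 (ENSG00000240498, chromosome 9, 21994778 to 22121097, plus strand, GRCh38) is a long noncoding RNA that overlaps CDKN2B. In HCT116 it had 7 and 3 reads in the control libraries (95% Poisson intervals 2.81 to 14.4 and 0.619 to 8.77) and 43 and 30 reads in the overexpression libraries (31.1 to 57.9 and 20.2 to 42.8). Its mean was 0.0469 ± 0.0227 FPKM (SD, n = 2) in controls and 0.357 ± 0.0855 FPKM (SD, n = 2) with circ86591. The ratio of read rates was 7.44 (95% interval 3.83 to 16.2), and these intervals cover counting error only. The gene lay below the filter on low values. In the limma fit without that filter it was 0.37 ± 0.09 (SE) higher with an adjusted p of 0.560. That fit adds 1 before the log, so it understates the change of a gene at such low values. With 43 and 30 reads the gene met the filter of the voom test on recovered reads, whose value for it is not given here. This is a gene-level count and not a measure of the circle. Reads from the circ86591 sequence of the vector could be assigned to this gene and could not be told apart here. CDKN2B-AS1 in LoVo was not analysed here, so the knockdown of the target was not checked.

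**Figure D2:**
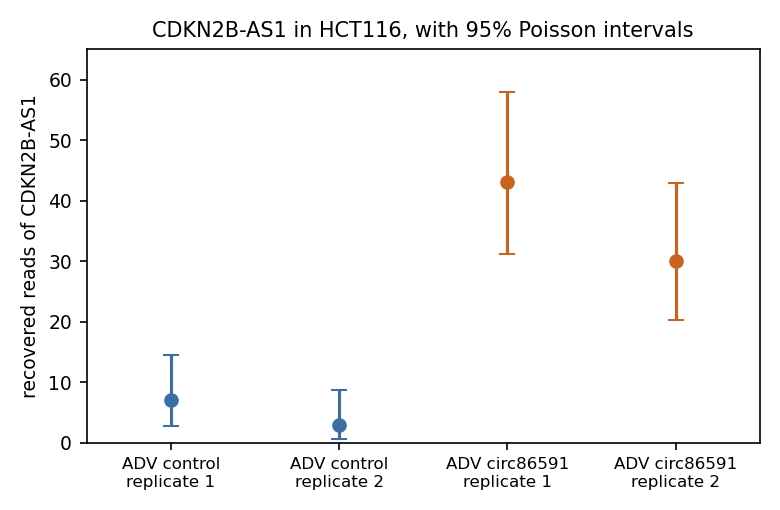
Reads of CDKN2B-AS1 recovered in each of the 4 HCT116 libraries (points, reads per library) with exact 95% Poisson intervals (bars). The control libraries had 7 and 3 reads and the libraries with circ86591 had 43 and 30.

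The protein-coding genes of the locus showed no difference that passed the test in LoVo. CDKN2A and CDKN2B, which encode inhibitors of CDK4 and CDK6, were −0.40 ± 1.22 and −0.40 ± 1.22 (log2, SE, n = 2 against 2) on the deposited scale. Both already lay above the median gene there, which was at −0.70. Rescaling moved that median to −0.03 and with it turned both genes positive, to 0.39 ± 0.24 and 0.40 ± 0.23. CDKN2A was −0.15 with a further correction for gene length and GC content. MTAP, an enzyme of methionine salvage, was −1.51 ± 1.22 as deposited and −0.73 ± 0.36 on the rescaled values, where it was −1.17 without knockdown replicate 1 and −0.28 without knockdown replicate 2. In HCT116, CDKN2A was 0.10 ± 0.05 and CDKN2B 0.10 ± 0.09 higher with circ86591. Neither passed under any of 20 settings, and with voom on recovered reads their adjusted p was 0.646 and 0.739. HCT116 CDKN2B was 0.04 and 0.16 higher without control replicates 1 and 2, and 0.18 and 0.02 higher without overexpression replicates 1 and 2. HCT116 MTAP was 0.18 ± 0.05 higher, from 17.5 ± 0.0339 to 19.9 ± 0.854 FPKM (SD, n = 2). Its limma adjusted p was 0.359 on log2 FPKM and 0.0254 with voom on recovered reads, and ran from 0.00264 to 0.706 over all alternatives.

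The LoVo knockdown comparison asked what changed when circ86591 was targeted. The type III interferons IFNL3 and IFNL2, secreted cytokines of antiviral defence, rose after the ASO. IFNL3 went from 0.587 ± 0.0961 to 23.8 ± 2.25 rescaled TPM (SD, n = 2), a log2 change of 3.96 ± 0.23 (SE), and IFNL2 from 0.540 ± 0.250 to 24.2 ± 5.03, a log2 change of 4.03 ± 0.27. Their adjusted p values in limma were 0.0414 and 0.0458. These paralogs are nearly identical on chromosome 19, so reads could be split between them and their separate values are uncertain. On the rescaled values both calls ended with a gene length correction (adjusted p 0.0740 for each), with a length and GC correction (0.120), with a replicate block (0.123) and without either control library. With either correction both log2 changes stayed at 3.30 or higher. For the left-out controls the adjusted p was 0.513 for each without control replicate 1 and 0.713 for each without control replicate 2, with log2 changes between 3.75 and 4.01. Neither gene was among those tested on the rescaled values when a knockdown library was left out. Over all alternatives the adjusted p ran from 0.0117 to 1.00 for IFNL3 and from 0.00103 to 1.00 for IFNL2.

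No LoVo gene passed as deposited, so IFNL3, IFNL2 and the genes of this paragraph were named for the smallest unadjusted p there, and those of this paragraph did not pass on the rescaled values either. IFNL1, the other type III interferon here, was 3.91 ± 0.33 higher, from 2.08 ± 1.18 to 43.6 ± 2.35 rescaled TPM. The chemokine CCL5, which attracts T cells, was 3.24 ± 0.37 higher (16.3 ± 2.57 and 106 ± 72.0 deposited TPM), and CCL22, a ligand of CCR4, was 3.22 ± 1.31 higher. The interferon-induced GTPase GBP5 was 2.33 ± 0.28 higher. P2RY11, an ATP receptor, and the cancer-testis gene CSAG3 were 3.43 ± 0.54 and 2.32 ± 0.25 higher. In the other direction, IL6ST, the shared receptor subunit gp130 of the IL-6 family, was −3.00 ± 0.25, from 16.3 ± 2.83 to 1.14 ± 0.131 rescaled TPM. ERCC6L, a mitotic DNA translocase, was −1.71 ± 0.41. Other places went to AL136295.1 (−2.64 ± 0.59), the readthrough gene SENP3-EIF4A1 (−3.74 ± 0.95), AC104109.3 (−2.67 ± 1.32), AC118553.2 (−2.95 ± 0.82) and AC007192.1 (−2.82 ± 0.66), clone-named genes and a readthrough whose reads could belong to neighbouring genes. Several of these genes passed on the rescaled values only when a knockdown library was left out. Such fits compare 1 knockdown library with 2 controls and take their spread from the controls, so they are no evidence for single genes. Without knockdown replicate 2 the library kept was knockdown replicate 1, with 73.6% mitochondrial TPM. Leaving out 1 library moved the rescaled values of 4 of these genes by more than 1.5 times. AC104109.3 was −4.63 without control replicate 1 and −0.53 without control replicate 2, and without knockdown replicates 1 and 2 ERCC6L was −2.64 and −1.09, AL136295.1 −3.96 and −1.68 and SENP3-EIF4A1 −2.29 and −5.04. Over all alternatives the adjusted p of IFNL1 and CCL5 ran from 0.0165 to 1.00 and that of IL6ST from 0.0133 to 1.00.

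Interferon-stimulated genes, the effectors that cells make in response to interferon, stood above other genes after the knockdown. The median of the 27 tested members was 0.88, a fold of 1.84, and limma's camera gave an adjusted p of 5.37e-11 on the rescaled values and 2.47e-10 as deposited. The call was lost when the correlation between genes was estimated (adjusted p = 0.646 with an estimated correlation on the rescaled values and 0.989 as deposited). The estimated correlation was 0.962 as deposited, against the preset of 0.01. With 2 libraries in each group almost no list could pass that test. With no filter on low values the list was 0.54 above all genes, against 0.81 with the filter as deposited, and still passed (0.00885). ISG15, a ubiquitin-like modifier, was 2.65 ± 0.45 higher. OASL, a relative of the 2'-5' oligoadenylate synthetases, was 2.46 ± 0.25 higher, IFIT2, which binds foreign RNA, 2.23 ± 0.23, and MX2, a dynamin-like GTPase, 1.94 ± 0.31. On the rescaled values 0 members passed over all genes tested and 16 were higher adjusted over the list alone, against 0 and 0 as deposited. The list median was 0.75 and 0.73 for knockdown replicate 1 against each control, and 1.10 and 1.08 for knockdown replicate 2, which held 20.8% mitochondrial TPM.

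A further 6 lists lay above other genes with camera as deposited. Each of them lost its call in the same way (adjusted p = 0.989 with an estimated correlation as deposited). ATF4 and amino acid response genes had a rescaled median of 0.61 over 23 members, 8 of them higher adjusted over the list alone. They included the stress-induced chromatin factor NUPR1 (2.82 ± 0.51) and PPP1R15A (1.73 ± 0.25), which directs dephosphorylation of eIF2alpha, while the cystine transporter SLC7A11 was −0.67 ± 0.42. With no filter on low values the ATF4 list was 0.33 above all genes, against 0.56 as deposited with the filter, and lost its call (adjusted p 0.0848). NF-kB and inflammatory genes had a median of 0.45 over 21 members, 2 of them higher adjusted over the list alone. NFKB2, which encodes the p52 precursor, was 1.68 ± 0.31 higher, and the adhesion molecule ICAM1 was 1.13 ± 0.36 higher. NRF2 targets and iron storage genes had a median of 0.52 over 16 members, 1 of them higher adjusted over the list alone, with the oxidative stress gene OSGIN1 at 1.87 ± 0.37. With no filter both calls ended, at 0.14 above all genes for NF-kB against 0.42 (adjusted p 0.179) and 0.23 for NRF2 against 0.45 (0.179). Replication-dependent histones had a median of 0.55 over 13 members, 1 higher adjusted over the list alone, with the linker histone HIST1H1E at 1.36 ± 0.46. Polyadenylated RNA was sequenced and most transcripts of these genes lack a poly(A) tail, so this list may not reflect histone expression. Relative to all genes the histone list was 0.28 with the gene length correction (adjusted p 0.190) and 0.28 with the length and GC correction (0.319), which ended its call. As deposited it was 0.62, and 0.93 without control replicate 2, 0.37 without knockdown replicate 1 and 1.03 without knockdown replicate 2. The 50 cytosolic ribosomal proteins had a median of 0.60 with 0 passing adjusted over the list alone, and with quantile normalization the list was 0.16 above all genes (adjusted p 0.0916). With no filter it was 0.21, against 0.49 as deposited with the filter, and still passed (0.0367). LoVo changes followed GC content (Spearman correlation 0.475 across genes, rescaled) and gene length (−0.245). With both trends removed the ribosomal list was 0.54 above all genes, against 0.63 before. RPL13 was 1.63 ± 0.62 higher, and RPL7 was −0.05 ± 0.29.

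The mitochondrially encoded genes were the other list of these 6, with a rescaled median of 1.01 and an adjusted p of 0.164 on that scale. MT-CO2, a subunit of cytochrome c oxidase, was 1.59 ± 1.37 higher. The direction of this list rested on single libraries. Its median relative to all genes was 0.89 as deposited, −0.18 without control replicate 1, 2.12 without control replicate 2, −0.80 without knockdown replicate 1 and 2.65 without knockdown replicate 2, and its call ended with no filter (0.62, adjusted p 0.108). Apart from this list and the interferon-stimulated genes, the lists above had a median under 0 on the deposited scale, against −0.70 for all genes. Without knockdown replicate 2 the NF-kB list was 0.13 above all genes as deposited (adjusted p 0.383) and 0.38 rescaled (0.101), and without knockdown replicate 1 it was 0.80 and 0.79. Without knockdown replicate 2 the NRF2 list was 0.22 as deposited (0.142) and 0.38 rescaled, where it passed (0.0377).

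**Figure D3:**
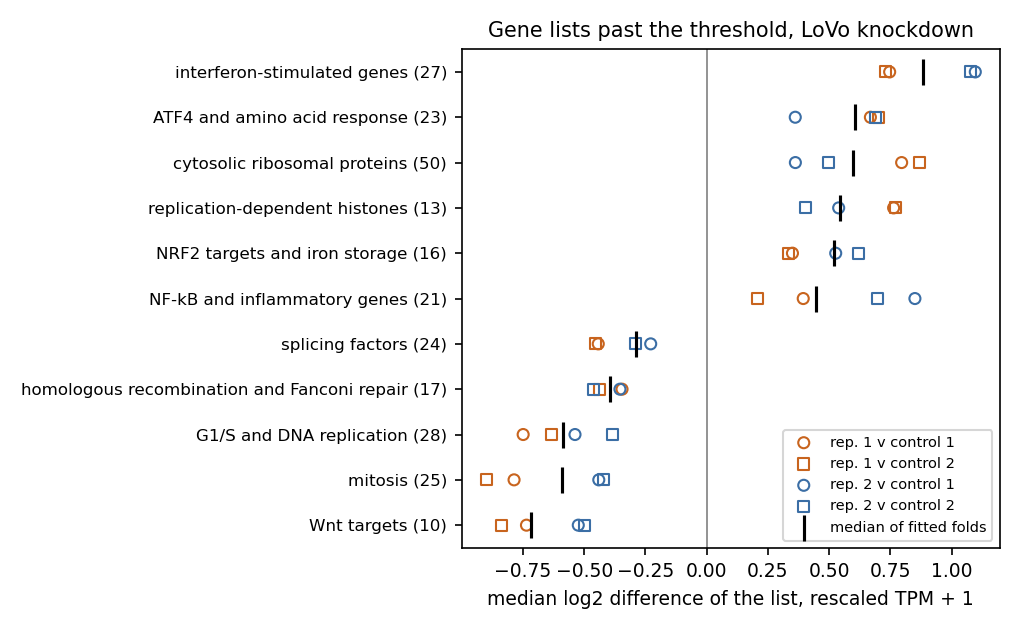
Median log2 change of 11 of the 12 lists that passed camera in LoVo, on values rescaled by median-of-ratios (black bars, x axis, log2 of rescaled TPM + 1), with the medians of the 4 pairs of a knockdown and a control library (open symbols). The interferon-stimulated genes had a median of 0.88 and the G1/S and mitosis lists medians of −0.59 and −0.59, and the mitochondrially encoded genes are not drawn, because their pair medians ran from −1.96 to 4.08.

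Genes of cell division were lower than other genes after the knockdown. The 28 G1/S and DNA replication genes had a rescaled median of −0.59 (camera adjusted p 5.79e-07), with 0 passing over all genes tested and 6 lower adjusted over the list alone. That call was lost with adjusted p = 0.646 with an estimated correlation. CCNE2, the cyclin partner of CDK2 at S phase entry, was −1.40 ± 0.23. The clamp loader subunit RFC3 was −1.49 ± 0.32, RRM2, the small subunit of ribonucleotide reductase, −1.14 ± 0.24, and the replication origin factor MCM10 −1.08 ± 0.26. The 25 mitosis genes also had a median of −0.59 (adjusted p 3.16e-06, and adjusted p = 0.646 with an estimated correlation), with 0 passing adjusted over the list alone. The spindle protein NUSAP1 was −1.26 ± 0.37, DNA topoisomerase TOP2A −1.13 ± 0.23, cyclin CCNA2 −1.04 ± 0.26 and the kinesin KIF23 −0.98 ± 0.25. Without knockdown replicate 1 the mitosis list was −0.40 from all genes as deposited, against −0.62 with all libraries. For knockdown replicate 2 alone, the medians against the controls were −0.54 and −0.38 for G1/S and −0.44 and −0.42 for mitosis.

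Wnt targets, repair genes and splicing factors made up the rest of the lower lists. The Wnt targets had a rescaled median of −0.72 (adjusted p 0.00684, and adjusted p = 0.646 with an estimated correlation), with 1 lower adjusted over the list alone. Without knockdown replicate 1 the list was −0.37 from all genes on the rescaled values, against −0.68 with all libraries. With no filter it was −0.34, against −0.61 as deposited with the filter, and lost its call (adjusted p 0.0748). LGR5, the intestinal stem cell receptor for R-spondins, was −1.64 ± 0.36, the receptor TNFRSF19 −1.45 ± 0.48 and the Wnt transcription factor LEF1 −1.08 ± 0.32. The 17 genes of homologous recombination and Fanconi repair had a median of −0.40 (adjusted p 0.00800, and adjusted p = 0.646 with an estimated correlation), with 0 passing adjusted over the list alone. BARD1, the partner of BRCA1, was −1.31 ± 0.30 and XRCC2, which acts in homologous recombination, −0.94 ± 0.23. The 24 splicing factors had a median of −0.29, with an adjusted p of 0.0382 as deposited and 0.0559 on the rescaled values. It had adjusted p = 0.989 with an estimated correlation as deposited and 0.756 rescaled. Among them SRSF7 was −1.13 ± 0.34 and TRA2B −0.96 ± 0.28. The repair list, −0.38 from all genes as deposited and −0.36 rescaled, kept its direction and lost its call without knockdown replicate 2 (−0.31, adjusted p 0.368 as deposited, and −0.41, 0.169 rescaled), with the length and GC correction (−0.27, 0.197) and with no filter (−0.65, 0.343). The splicing list, −0.40 from all genes as deposited, was −0.47 (adjusted p 0.176) without control replicate 2, −0.15 (0.292) without knockdown replicate 1 and −0.61 without knockdown replicate 2. It also did not pass with no filter (−0.67, 0.139) or a pseudocount of 0.1 (−0.27, 0.0553). On the rescaled values the splicing list did not pass with the length correction (−0.15, 0.102) or the length and GC correction (−0.20, 0.595).

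As deposited, limma called 0 of 11918 LoVo genes higher and 0 lower, with 19 higher and 54 lower at an unadjusted p under 0.05. On the rescaled values it called 2 of 11762 higher and 0 lower, with 1052 and 1093 at an unadjusted p under 0.05. The groups did not overlap for 23.3% of genes as deposited and 55.3% rescaled, where chance gives 33.3%. Without knockdown replicate 2, the rescaled counts were 623 higher and 519 lower, and without knockdown replicate 1 they were 14 and 11. As deposited they were 0 and 22 without knockdown replicate 2, and 1 and 0 without knockdown replicate 1.

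The HCT116 comparison asked what changed with the vector carrying circ86591. Changes were small, and no gene passed limma on log2 FPKM. The log2 changes and SE here are from that fit. They are set beside the adjusted p of a test on recovered reads (limma voom, chosen after the data were seen). HSPA5, the main chaperone of the endoplasmic reticulum (chromosome 9, 125234853 to 125241330), was lower, from 419 ± 6.12 to 319 ± 5.36 FPKM (SD, n = 2), a log2 change of −0.39 ± 0.03. INSIG1, which holds SREBP in the endoplasmic reticulum, went from 87.3 ± 2.82 to 59.4 ± 2.53 FPKM (−0.55 ± 0.05), and FDFT1, squalene synthase, from 58.1 ± 0.639 to 45.5 ± 0.675 FPKM (−0.35 ± 0.04). DCBLD2, a transmembrane receptor, was higher, from 39.4 ± 0.664 to 53.4 ± 1.05 FPKM (0.43 ± 0.04).

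The voom adjusted p was 9.41e-12 for HSPA5, 5.24e-10 for INSIG1, 4.47e-06 for FDFT1 and 5.43e-10 for DCBLD2. With limma on log2 FPKM it was 0.200, 0.212, 0.213 and 0.212. Over all alternatives it ran from 1.44e-33 to 0.636 for HSPA5, from 6.98e-22 to 0.636 for INSIG1, from 2.94e-08 to 0.665 for FDFT1 and from 4.26e-22 to 0.636 for DCBLD2. The other lower genes were ARL6IP1 (−0.41 ± 0.04), an endoplasmic reticulum membrane protein, the phosphate transporter SLC20A1 (−0.39 ± 0.04), the ERK phosphatase DUSP5 (−0.33 ± 0.03), the metallothionein MT2A (−0.30 ± 0.03) and the circadian factor DBP (−0.47 ± 0.05). The other higher genes were MT-CYB (0.26 ± 0.03), the apocytochrome b of complex III, the mitochondrial sulfurtransferase TST (0.39 ± 0.05), the neurotensin receptor NTSR1 (0.30 ± 0.04), the lipid transfer protein CPTP (0.62 ± 0.08), the homeobox gene MKX (0.44 ± 0.06), ITPRIPL2 (0.38 ± 0.05) and the helix-loop-helix inhibitor ID3 (0.29 ± 0.04). All of these passed voom and did not pass limma on log2 FPKM, where they were named for the smallest unadjusted p in these same libraries. Of these genes and MTAP, 12 also passed each of the 4 voom fits that left out 1 library, which is not independent evidence. MT-CYB was 0.14 with quantile normalization (adjusted p 0.00226), and the list of mitochondrially encoded genes did not pass (0.768), with 4 higher and 4 lower adjusted over the list alone. That list passed above other genes with the gene length and GC correction (0.0319, and adjusted p = 0.639 with an estimated correlation). CPTP and ID3 passed in 3 of those fits, TST and MKX in 2, and MTAP in 1.

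Mitosis genes were lower with circ86591. All 25 tested members lay below the median gene, with a list median of −0.26 (camera adjusted p 1.93e-13, and adjusted p = 0.491 with an estimated correlation). With limma on log2 FPKM 0 passed over all genes tested and 12 were lower adjusted over the list alone, and with voom 9 and 21. UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, was −0.36 ± 0.04, the kinase AURKB −0.30 ± 0.05, the kinetochore protein CENPF −0.28 ± 0.05 and TOP2A −0.23 ± 0.05. The G1/S and DNA replication list did not pass, with a median of −0.03 and an adjusted p of 0.765.

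Cholesterol synthesis genes were also lower, with a median of −0.19 over 21 members (camera adjusted p 1.62e-08, and adjusted p = 0.491 with an estimated correlation). With limma on log2 FPKM 0 passed over all genes tested and 11 were lower adjusted over the list alone, and with voom 11 and 13. Besides INSIG1 and FDFT1, the sterol carrier STARD4 was −0.36 ± 0.06. The 16 endoplasmic reticulum chaperones had a median of −0.07 (adjusted p = 0.491 with an estimated correlation), with 2 lower adjusted over the list alone and 4 called by voom. HSP90B1, the chaperone GRP94, was −0.23 ± 0.03. Replication-dependent histones had a median of −0.25 over 7 members (adjusted p = 0.491 with an estimated correlation), 2 of them lower adjusted over the list alone, with the linker histone HIST1H1C at −0.45 ± 0.06. The histone list was −0.46 from all genes with voom and −0.13 with a filter at a mean of 5. As in LoVo, polyadenylated RNA was sequenced, so this list may not reflect histone expression.

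The p53 targets had a median of −0.11 over 22 members (adjusted p = 0.491 with an estimated correlation), 4 of them lower adjusted over the list alone. The stress cytokine GDF15 was −0.36 ± 0.06, the growth arrest gene GADD45A −0.26 ± 0.05, the kinase PLK3 −0.30 ± 0.06 and the apoptosis effector BAX −0.26 ± 0.05. The 50 cytosolic ribosomal proteins had a median of −0.08 (adjusted p = 0.542 with an estimated correlation), with 0 passing adjusted over the list alone and 33 with voom. Among them RPS13 was −0.14 ± 0.03 and RPL19 −0.12 ± 0.03. With quantile normalization the ribosomal list was −0.01 from all genes and lost its call (adjusted p 0.793). The list fixed as nuclear long noncoding RNAs had a median of −0.09 over 8 members (adjusted p = 0.618 with an estimated correlation). It also held hosts of small nucleolar RNAs, such as GAS5 at −0.31 ± 0.03, which was lower adjusted over the list alone. Where its members lie in the cell was not measured, so the name is only a label. The 14 epithelial markers (median −0.07, adjusted p = 0.542 with an estimated correlation, 0 passing adjusted over the list alone) included the tight junction proteins CLDN4 (−0.22 ± 0.05) and OCLN (−0.19 ± 0.06). The noncoding RNA list was −0.03 (adjusted p 0.445) without overexpression replicate 2, −0.15 without overexpression replicate 1 and −0.07 (0.0675) without control replicate 1. The epithelial list lost its call without control replicate 2 (−0.06, adjusted p 0.180), without overexpression replicate 1 (−0.06, 0.0912), with no trend (−0.07, 0.125) and with quantile normalization (−0.02, 0.257).

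Wnt targets and interferon-stimulated genes were among the 4 lists above other genes in HCT116. The 11 Wnt targets had a median of 0.18 (adjusted p = 0.491 with an estimated correlation), with 0 passing adjusted over the list alone. The Wnt list was 0.05 with a filter at a mean of 5, which ended its call (adjusted p 0.362), 0.14 without control replicate 1 (0.0523), 0.15 without overexpression replicate 1 (0.112) and 0.11 without overexpression replicate 2 (0.0480). AXIN2, the feedback inhibitor of Wnt signaling, was 0.24 ± 0.07 higher, and the receptor kinase EPHB2 0.18 ± 0.08. The 17 interferon-stimulated genes had a median of 0.14 (adjusted p = 0.491 with an estimated correlation), with 0 passing adjusted over the list alone and 4 with voom. With voom the interferon list was 0.23 from all genes without control replicate 2 and 0.08 without overexpression replicate 1. IFI6, an antiviral membrane protein, was 0.52 ± 0.13 higher and OAS3, an oligoadenylate synthetase, 0.30 ± 0.08. ATF4 and amino acid response genes had a median of 0.09 over 21 members (adjusted p = 0.542 with an estimated correlation), with 4 higher and 2 lower adjusted over the list alone. The pseudokinase TRIB3 was 0.40 ± 0.08 and the serine synthesis enzyme PSAT1 0.36 ± 0.08 higher, while PPP1R15A was −0.33 ± 0.05. MYC targets and ribosome biogenesis genes had a median of 0.04 over 22 members (adjusted p = 0.542 with an estimated correlation), with 0 passing adjusted over the list alone and MYBBP1A, a nucleolar protein, 0.27 ± 0.06 higher. The ATF4 list was 0.07 (adjusted p 0.123) without overexpression replicate 2. The MYC list was 0.05 (0.253) without control replicate 1, 0.06 without control replicate 2 and 0.02 (0.211) without overexpression replicate 2. Its call also ended with a filter at a mean of 5 (0.05, 0.0563), with no trend (0.04, 0.0993) and with protein-coding genes alone (0.03, 0.0756).

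**Figure D4:**
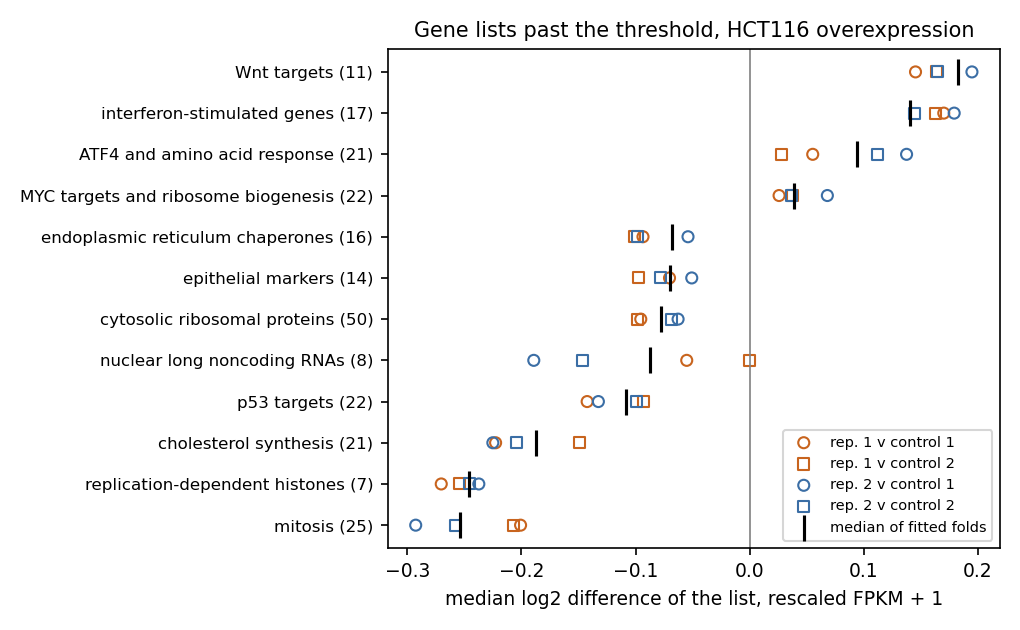
Median log2 change of each list that passed camera in HCT116 (black bars, x axis, log2 of FPKM rescaled by median-of-ratios + 1), with the medians of the 4 pairs of an overexpression and a control library (open symbols). The mitosis list had a rescaled median of −0.25 and the cholesterol synthesis list of −0.19, and the Wnt targets had the highest, 0.18.

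With limma on log2 FPKM, 0 of 14338 HCT116 genes were called higher and 0 lower, with 698 higher and 996 lower at an unadjusted p under 0.05. With voom, 117 of 16332 genes were higher and 201 lower, of which 4 and 8 changed at least 2-fold. The groups did not overlap for 43.6% of genes, where chance gives 33.3%. The voom counts were 24 and 60 without control replicate 1, 38 and 107 without control replicate 2, 167 and 193 without overexpression replicate 1, and 103 and 221 without overexpression replicate 2.

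The cell lines were set side by side because the treatments were meant to lower circ86591 in LoVo and to raise it in HCT116. Across the 10210 genes tested in both, the log2 changes had a Pearson correlation of −0.0346 across genes, just outside the highest absolute value of 0.0332 that 1000 random pairings of genes gave. Genes are not independent replicates. The correlation was −0.0507 with median-of-ratios scaling and −0.0620 with length and GC corrected in both. It ran from −0.0836 without HCT116 overexpression replicate 2 to 0.0211 without HCT116 overexpression replicate 1. With limma on the deposited values 0 genes were called in both lines, and at an unadjusted p under 0.05 there were 2 in the same and 1 in the opposite direction. With median-of-ratios in LoVo and voom in HCT116, 0 genes were called in both, and 143 and 192 had an unadjusted p under 0.05, where independence gives 150 and 149. With median-of-ratios scaling in both lines these counts were 90 and 137, where independence gives 99.1 and 97.4. With length and GC corrected in both they were 64 and 125, against 79.4 and 80.5. Since genes are not independent, the excess in the opposite direction was not tested.

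Of 30 lists tested in both lines, 6 passed camera in both at the preset correlation. With an estimated correlation 0 passed in either line, where the design let almost no list pass. The mitosis genes were lower in both (−0.59 and −0.26), and the ATF4 genes (0.61 and 0.09) and interferon-stimulated genes (0.88 and 0.14) higher in both. The ribosomal proteins were higher in LoVo and lower in HCT116 (0.60 and −0.08), as were the histones (0.55 and −0.25), and the Wnt targets went the other way (−0.72 and 0.18). The tables were normalized separately and the library protocols of the lines differed, so the difference between lines was not tested.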

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

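The median-of-ratios settings with left-out libraries, block, length or GC correction, the removal of mitochondrially encoded genes, voom and the HCT116 length and GC correction were chosen after the data were seen. The test on the other deposited table could not be run, since each table holds 1 cell line. Of the alternative values of named genes, 302 in LoVo and 250 in HCT116 kept direction and side of the threshold, 31 and 111 passed it only in the alternative, and 22 and 0 reversed. No gene passed in the main fits, so keeping its side meant still failing, and no call could be lost. The IFNL3 and IFNL2 calls that ended under alternatives of the rescaled values are counted as kept. Of the alternative values of the lists, 206 and 207 kept both, 41 and 32 no longer passed and 4 and 0 reversed. Except for the fewer or more genes that a filter tests, the cause was not tested. The LoVo depth is unknown.

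In LoVo the genes called higher numbered 96 with no filter, 2 with median-of-ratios scaling, 2 with quantile normalization and 15 with mitochondrially encoded genes removed, against 0 as deposited. The genes called lower numbered 124 with no filter and 4 with mitochondrially encoded genes removed. With a replicate block 0 were called in either direction, on deposited values or after median-of-ratios scaling, and after that scaling 0 with the length correction and 0 with the length and GC correction. Leaving out 1 library gave 0 to 1 higher and 0 to 22 lower. After median-of-ratios scaling it gave 14 higher and 11 lower without knockdown replicate 1, 623 and 519 without knockdown replicate 2, and 0 and 0 without either control. Of 12 lists past the threshold, 5 still passed with no filter, where 6 passed in all, and 0 with the estimated correlation. The mitochondrially encoded list, at 0.89 as deposited, was −0.18 without control replicate 1 and −0.80 without knockdown replicate 1 (highest 2.65), and −0.10 and −0.81 after median-of-ratios scaling, with a highest value of 2.94.

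CDKN2A, −0.40 as deposited, was 0.39 with median-of-ratios scaling, 0.39 with that and a replicate block, 0.26 with quantile normalization, 0.089 with mitochondrially encoded genes removed and 0.15 with the length correction. It ran from −1.43 to 0.63 with 1 library left out, and after median-of-ratios scaling was 0.48, 0.28, 0.57 and 0.23 without control replicates 1 and 2 and knockdown replicates 1 and 2. CDKN2B, −0.40 as deposited, was 0.40 with median-of-ratios scaling, 0.40 with that and a replicate block, 0.24 with quantile normalization, 0.10 with mitochondrially encoded genes removed, 0.49 with the length correction and 0.63 with the length and GC correction. It ran from −1.36 to 0.57 with 1 library left out, and after median-of-ratios scaling was 0.32, 0.47, 0.51 and 0.32 in the same order.

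In HCT116 the genes called higher numbered 2 with quantile normalization, 8 with no trend, 13 with protein-coding genes alone, 117 with voom and 134 with voom and a replicate block, against 0 with limma on log2 FPKM. The genes called lower numbered 1 with a filter at a mean of 5, and 3, 6, 47, 201 and 277 with the same 5 settings. Voom without control replicates 1 and 2 and overexpression replicates 1 and 2 called 24, 38, 167 and 103 higher and 60, 107, 193 and 221 lower. With the estimated correlation 0 of 12 lists passed.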

Other observations

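The KEGG tests, the genes named in the next 2 paragraphs, the tests of gene length and GC content in LoVo and the comparison of the interferon-stimulated genes with HCT116 were chosen after the results were seen.

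The following genes were picked for their values in LoVo, and none passed limma on the rescaled values. IFNB1, the type I interferon beta, had 1.40 ± 0.728 TPM in controls and 7.84 ± 6.17 TPM after knockdown (SD, n = 2), 2.28 ± 0.23 higher on the rescaled log2 scale. The chemokine CXCL10 was 2.53 ± 0.29 higher and ISG20, an antiviral exonuclease, 2.58 ± 0.22 higher. IRF7, a transcription factor of interferon genes, was 1.76 ± 0.24 higher, RELB, an NF-kB subunit, 1.53 ± 0.23, and the stress factors ATF3 and DDIT3 1.49 ± 0.26 and 1.04 ± 0.25.

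Among 340 KEGG pathways in LoVo, 17 lay above and 2 below other genes with camera as deposited, and 19 and 7 of 339 on the rescaled values. The lowest adjusted p on the rescaled values were those of the COVID-19 pathway (0.50 above all genes, adjusted p 1.55e-06) and the ribosome (0.47, 5.63e-06), with adjusted p = 0.785 with an estimated correlation for both. The 54 genes of RIG-I-like receptor signaling, which senses RNA in the cytosol, had a median 0.39 above all genes on the rescaled values (adjusted p 0.00659), and the 50 genes of cytosolic DNA sensing a median 0.34 above (0.0105). The proteasome lay 0.29 above (0.00520), and DNA replication −0.33 (0.0174) and sphingolipid metabolism −0.47 (0.0156) from the median of all genes. As deposited the proteasome (adjusted p 0.0684) and DNA replication (0.0676) did not pass. With length and GC corrected, the ribosome was 0.30 above all genes, RIG-I-like receptor signaling 0.34 and cytosolic DNA sensing 0.21. For RIG-I-like receptor signaling, cytosolic DNA sensing, the proteasome and DNA replication the adjusted p = 0.785 with an estimated correlation, and for sphingolipid metabolism 0.808. In HCT116, 0 of 331 pathways lay above and 2 below, the ribosome (−0.07, adjusted p 4.58e-07) and the COVID-19 pathway (−0.07, adjusted p 1.47e-05), which includes the ribosomal proteins, and the adjusted p = 0.999 for both with an estimated correlation.

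Interferon-stimulated genes lay above other genes in the LoVo knockdown libraries. The mitochondrial share was not tested as a cause, and the pair of libraries closest in it (20.8% and 18.2%) had a list median of 1.10. With gene length and GC trends removed the median was 1.03, outside the −0.17 to 0.28 that held 95% of 10000 random lists matched on expression. The random lists here and below hold unrelated genes, and genes regulated together can leave such a range. It therefore does not test chance differences between libraries. Loss of the circular RNA stays open: the same list was 0.14 above other genes in HCT116 with the circ86591 vector, another cell line, and the level of the circle was not measured. A response to the oligonucleotide itself is an untested alternative, since 1 oligonucleotide was compared with 1 control.

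G1/S and mitosis genes lay below other genes in the LoVo knockdown libraries. After removal of gene length and GC trends their medians were −0.56 and −0.43, outside the random ranges of −0.19 to 0.20 and −0.19 to 0.24. Knockdown replicate 2, the library with the lower mitochondrial share, gave −0.38 or lower for both lists against each control, so the other knockdown library alone does not account for the pattern, and other effects tied to the mitochondrial share were not tested. Loss of circ86591, which was not measured, stays open as a cause: in HCT116, where the vector was meant to raise it, the mitosis list was lower too (−0.26) and the G1/S list did not pass (−0.03). An effect of the oligonucleotide was not tested.

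Mitosis and cholesterol synthesis genes lay below other genes in the HCT116 libraries with circ86591. With gene length and GC trends removed the medians were −0.26 and −0.19, outside the random ranges of −0.06 to 0.05 and −0.07 to 0.03. The weakest median over the 4 pairs of libraries and both lists was −0.15 and the strongest −0.29, which argues against 1 library alone. An effect of circ86591, whose level was not measured, stays open: in LoVo, where it was meant to be lowered, the mitosis list was lower as well (−0.59). The LoVo cholesterol list did not pass (rescaled median 0.18, adjusted p 0.215), except above other genes without knockdown replicate 1 (0.00133, and adjusted p = 0.565 with an estimated correlation). Differences in cell density between the cultures were not tested.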
